A study of Glycine max with 48 samples.

How the data were processed

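RNA was measured by paired-end sequencing, with reads of 150 bases, in sepals, anthers, ovaries and stigmas of soybean (Glycine max, cultivar Magellan). Each of the 16 groups (4 organs under 4 treatments) held 3 libraries, which gives 48 libraries in all. Per the labels, each library came from a pool of 10 to 15 flowers taken from 8 to 10 plants. The plants were assigned to treatments when the first flower opened, after 16 to 18 days of growth, and 4 growth chambers held the 4 treatments. Which chamber held which treatment is not given in the sources used here. If each treatment had a chamber of its own, chamber and treatment cannot be told apart in any comparison.

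The authors aligned the reads with HISAT2 2.2.1 and deposited FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library), with a separate file for each organ. The counting tool, the genome build and the annotation release are not given in the sources used here. Each file held 57147 identifiers, of which 55897 began with GLYMA_ and 1250 with ENSRNA. The files hold identifiers and FPKM but no gene names. Of the identifiers, 0 of 57147 matched the reference gene table, and genes are given by identifier. Without names the 28 gene lists fixed in advance could not be built, and none of them was tested.

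Read counts and library totals were not analysed here, so the absolute depth of each library is unknown and no counting interval is given. Low FPKM values fell on regular steps, from which the depth of each library relative to the lowest of its organ was estimated. The highest relative depth was 1.30 among sepal libraries, 1.60 among anther libraries, 1.54 among ovary libraries and 1.45 among stigma libraries. Values of exactly 0 also occurred in well expressed genes. Of genes with an organ mean of at least 5 FPKM, 273 of 19058 in the sepal, 264 of 13686 in the anther, 249 of 19861 in the ovary and 261 of 19373 in the stigma were at 0 in at least 1 library. A gene at 0 is therefore described as listed at 0, and no fold is given against a group whose libraries are all at 0.

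Each organ was fitted alone on its 12 libraries with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), on log2(FPKM + 1), with a mean-variance trend and robust moderation. A gene was tested if its mean reached 1 FPKM in at least 1 of the 4 groups of the organ. This filter was set on all 12 libraries of the organ, also where a library was left out. Genes with a Benjamini-Hochberg adjusted p under 0.05 in limma's two-sided moderated test were called higher or lower. Contrasts were each stress against control, combined stress against heat and against water deficit, and the interaction of heat and water deficit. The response to combined stress in the anther, ovary or stigma minus that in the sepal was tested on 24 libraries. A log2 fold change is a difference of mean log2(FPKM + 1), and SE is its standard error from limma. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

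The filter, the model, the threshold, the contrasts, the rule for named genes and most alternatives were fixed before the data were examined. By that rule a named gene had to pass the threshold, reach a mean of 5 FPKM in the higher group, and have the 3 libraries of 1 group all above the 3 of the other. For the interaction and for differences between organs, the threshold and the mean alone applied. Without gene descriptions, at most 2 genes higher and 2 lower were named per comparison, those with the largest log2 fold changes, and the text leaves some of them out. The full profile of a gene over organs and treatments, and any gene said to have been chosen after its values were seen, fall outside this rule.

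The groups of genes by organ were defined after the data were seen, from means over the 12 libraries of each organ. A sepal-enriched or anther-enriched gene had a mean of at least 5 FPKM in that organ and at least 8-fold over every other organ, which gave 384 and 1325 genes. A pistil-enriched gene met this in both the ovary and the stigma against the sepal and the anther (151 genes). A broadly expressed gene had at least 5 FPKM in every organ with organ means within 2-fold (4240 genes). Stressed libraries enter these means, so a gene that rose strongly in another organ can drop out of a group. Groups were compared with all other tested genes by limma's camera with a preset correlation of 0.01, with adjustment over 64 tests. With the correlation estimated from the residuals, no group test stayed below an adjusted p of 0.05 and the lowest adjusted p was 0.0957. The share of summed FPKM from anther-enriched genes was compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3.

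On simulated data with the spread of the real libraries, 50 genes were changed by each of several folds in each organ. At 2-fold, the combined-stress comparison recovered 84% of the changed genes in the sepal, 66% in the anther, 96% in the ovary and 76% in the stigma. At 1.5-fold, it recovered 34%, 12%, 36% and 34%. False calls were 5.92%, 7.48%, 3.57% and 3.16% of all calls in the same order. These rates hold for that setting and may not carry over to genes at lower levels or to comparisons in which many genes shift together.

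Alternatives fixed in advance were a pseudocount of 0.1 FPKM, no filter on low values, no trend or robust moderation, median-of-ratios rescaling, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Alternatives added after the data were seen were leaving out the anther-enriched genes and rescaling to the remaining FPKM, a 4-fold definition of the gene groups, and the estimated correlation.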

Results

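Gene expression was measured in 4 organs of the soybean flower, the sepal, anther, ovary and stigma, to compare their responses to water deficit, heat and both stresses together. Control plants grew at 28 °C by day and 24 °C by night and received 100% of the water available for transpiration. Plants under water deficit received 30% at those temperatures, heated plants were kept at 38 °C by day and 28 °C by night with full water, and plants under combined stress met both conditions. Every group held 3 libraries. The number of genes at 1 FPKM or more per library ranged from 29771 to 31827 in the sepal, 21198 to 28209 in the anther, 30513 to 31295 in the ovary and 30514 to 31587 in the stigma. Depth is known only in relative terms, and the most deeply sequenced library of an organ had between 1.30 and 1.60 times the depth of its lowest. Libraries of a group correlated on average at between 0.962 and 0.981, with the lowest value in the anther under heat (replicate 3).

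In control libraries the 50 genes with the highest FPKM held 24.5% ± 1.47 (SD, n = 3) of summed FPKM in the anther, 12.3% ± 0.871 in the sepal, 11.7% ± 0.575 in the ovary and 12.4% ± 0.253 in the stigma. The groups of organ-enriched genes differ in size, so their shares are not compared between groups. The 1325 anther-enriched genes held 55.6% ± 3.24 (SD, n = 3) of summed FPKM in control anthers. In control libraries the same genes held 2.80% ± 1.49 in the stigma, 1.01% ± 1.04 in the sepal and 0.405% ± 0.165 in the ovary. The sepal-enriched genes held 6.67% ± 1.03 in control sepals, and the pistil-enriched genes held 6.49% ± 0.101 in control ovaries and 5.19% ± 0.0831 in control stigmas. Among control sepals, replicate 3 stood apart, with 2.21% from anther-enriched genes against 0.311% and 0.510% in the others.

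Water deficit alone was compared with control to find the response to low water supply without heat. Few genes passed the threshold in any organ. In the sepal, GLYMA_16G162400 fell from 11.2 ± 3.29 to 1.82 ± 0.381 FPKM (log2 fold change -2.08, SE 0.22, limma adjusted p = 0.0063), and GLYMA_15G073100 rose from 1.58 ± 0.802 to 5.81 ± 0.828 FPKM (log2 fold change 1.44, SE 0.21, limma adjusted p = 0.0266). In the ovary, GLYMA_04G014000 rose from 2.39 ± 0.196 to 10.2 ± 1.81 FPKM (log2 fold change 1.71, SE 0.16, limma adjusted p = 0.00415), while GLYMA_16G061400 fell from 37.9 ± 20.9 to 1.40 ± 1.17 FPKM (log2 fold change -3.93, SE 0.47, limma adjusted p = 0.0207), and both belong to the sepal-enriched genes. In the stigma, GLYMA_20G204500 was at 75.4, 44.1 and 24.2 FPKM in the control libraries, and under water deficit it was listed at 0 in 2 libraries and at 0.0271 FPKM in the other (log2 fold change -5.46, SE 0.47, limma adjusted p = 0.0073). GLYMA_07G229000 rose in the stigma from 12.1 ± 0.881 to 32.8 ± 10.98 FPKM (log2 fold change 1.33, SE 0.20, limma adjusted p = 0.0294).

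Of the genes tested under water deficit, 28 were higher and 41 lower in the sepal (33179 tested), 23 and 55 in the ovary (33336 tested), and 19 and 36 in the stigma (33609 tested). In the anther, limma called 1 gene of 28529. Genes with an unadjusted p under 0.05 numbered 4183 in the sepal, 561 in the anther, 2625 in the ovary and 2869 in the stigma. The gene called in the anther, ENSRNA050030560, was listed at 0 in the 3 control libraries and stood at 5.27, 5.22 and 8.35 FPKM under water deficit. The 3 libraries of 1 group all lay above those of the other for 16.7% of tested genes in the sepal, 6.57% in the anther, 14.1% in the ovary and 12.9% in the stigma, where chance gives 10%. These counts are small and rest on single libraries: the sepal gave 12 genes without water-deficit replicate 1 and 294 without control replicate 1, the anther 0 without control replicate 2 and 7 without control replicate 3, the ovary 4 without control replicate 1 and 116 without control replicate 2, and the stigma 11 without control replicate 3 and 73 without water-deficit replicate 2. Median-of-ratios rescaling moved the directions to 31 higher and 29 lower in the sepal and to 11 and 44 in the stigma. Pistil-enriched genes held 5.78% ± 0.128 of ovary FPKM under water deficit, against 6.49% ± 0.101 in the control. In the stigma they held 4.46% ± 0.219 against 5.19% ± 0.0831. The libraries did not overlap in either organ, and these shares were not tested. Few of these genes were called, 0 higher and 3 lower in the ovary and 1 and 1 in the stigma. GLYMA_15G073100, GLYMA_16G061400 and GLYMA_07G229000 lost their call in 7, 6 and 8 of 13 alternatives, GLYMA_16G162400 in 1, and GLYMA_04G014000 and GLYMA_20G204500 in 0.

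Heat alone was compared with control in the same way, and it changed many genes in every organ. Some of the genes that rose went from near 0 to high levels. GLYMA_08G068800 rose in the anther from 0.241 ± 0.0291 to 133 ± 25.98 FPKM (log2 fold change 6.73, SE 0.31, limma adjusted p = 1.57e-06), and GLYMA_19G011400 rose there from 0.725 ± 0.5003 to 121 ± 25.1 FPKM (log2 fold change 6.16, SE 0.27, limma adjusted p = 1.31e-06). GLYMA_10G176400 rose in the sepal from 0.209 ± 0.194 to 150.03 ± 35.4 FPKM (log2 fold change 6.95, SE 0.26, limma adjusted p = 3.71e-07). GLYMA_17G252200 fell in the sepal from 90.1 ± 20.0 to 9.49 ± 1.70 FPKM (log2 fold change -3.11, SE 0.32, limma adjusted p = 0.000439), and GLYMA_06G004200 fell in the anther from 19.6 ± 5.83 to 0.394 ± 0.123 FPKM (log2 fold change -3.85, SE 0.27, limma adjusted p = 2.27e-05). GLYMA_01G121800 stood at 34.7, 28.3 and 30.3 FPKM in control stigmas and was listed at 0 in the 3 heated stigma libraries. It is an anther-enriched gene, at 531 ± 189 FPKM in control anthers and 189 ± 67.4 in heated ones, so anther material in the stigma samples is not excluded as its source.

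Under heat, 1364 genes were higher and 2384 lower in the sepal, 4146 and 1131 in the anther, 1998 and 3612 in the ovary, and 2274 and 2408 in the stigma. In the ovary, 8 of 151 pistil-enriched genes rose and 67 fell (median log2 fold change -0.36, camera adjusted p = 1.13e-08, and adjusted p = 0.0957 with an estimated correlation). Their share of FPKM was 6.14% ± 0.135 in heated ovaries and 6.49% ± 0.101 in the control, a difference that was not tested. In the stigma, 3 of 1244 tested anther-enriched genes rose and 124 fell (median -0.75, camera adjusted p = 1.37e-21, and adjusted p = 0.878 with an estimated correlation). Stigma control replicate 1 held 4.49% of FPKM from these genes, against 2.199% and 1.71% in the other controls. The heated stigmas held 0.857%, 2.08% and 1.63%, so the groups overlapped (exact two-sided permutation p = 0.2, n = 3). A median without that control is not given here, so how far this fall rests on it stays open. Among the sepal-enriched genes in the sepal, 70 rose and 48 fell (median 0.09, and -0.01 without control replicate 3). After median-of-ratios rescaling the counts were 1689 higher and 1651 lower in the sepal and 2718 and 1858 in the anther. With the anther-enriched genes left out and libraries rescaled to the remaining FPKM, they were 2783 and 2893 in the ovary. Summed FPKM averaged 631528 in control ovaries and 604831 in heated ones, and that rescaling also makes these sums equal. The totals ranged from 2096 (without heat replicate 3) to 3960 in the sepal, 2570 (without control replicate 1) to 6739 in the anther, 3406 (without control replicate 1) to 4280 in the ovary and 2272 (without control replicate 1) to 3528 in the stigma as single libraries were left out.

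Combined stress against control gave the highest number of called genes of the 3 stresses in each organ. A shared set of 528 genes rose in all 4 organs and 286 fell in all 4, of 24778 genes tested in every organ, where independent calls would give 14.6 and 10.1. GLYMA_10G176400, at 0.362 ± 0.200 FPKM or less in control groups, reached 385 ± 138 FPKM in the sepal, 139 ± 101.3 in the anther, 214 ± 138 in the ovary and 359 ± 220 in the stigma, with log2 fold changes of 8.27, 6.66, 7.12 and 8.03. GLYMA_08G068800 rose by log2 fold changes of 7.80, 7.73, 6.70 and 7.35 in the same order of organs. GLYMA_19G245400 fell in all 4 organs, for example from 95.9 ± 26.4 to 9.89 ± 1.94 FPKM in the stigma (log2 fold change -3.14, SE 0.21, limma adjusted p = 9.74e-06), and GLYMA_14G051900 fell from 950 ± 92.9 to 284 ± 99.3 FPKM in the ovary (log2 fold change -1.78, SE 0.28, limma adjusted p = 0.00108). Leaving out 1 replicate of every group gave between 196 (without replicate 2) and 327 (without replicate 1) shared genes in place of 814. Heat alone shared 97 higher and 41 lower genes over the 4 organs, with 0.662 and 0.521 given by independent calls, and the total of 138 was between 9 (without replicate 3) and 23 (without replicate 2) when 1 replicate of every group was left out. Water deficit shared 0.

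**Figure D1:**
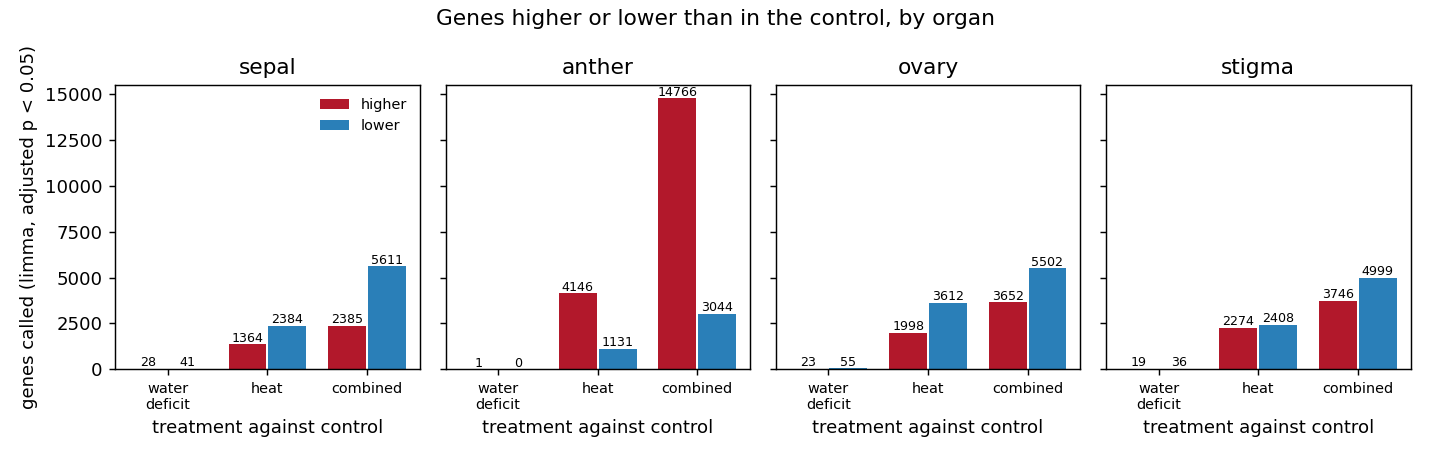
Bars give the number of genes that limma called higher (red) or lower (blue) than in the control, on the vertical axis, for each stress on the horizontal axis and each organ in its own panel. Combined stress gave the tallest bars in each organ, from 2385 higher and 5611 lower in the sepal to 14766 higher and 3044 lower in the anther.

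In the sepal, ovary and stigma, combined stress lowered more genes than it raised. The counts were 2385 higher and 5611 lower in the sepal, 3652 and 5502 in the ovary, and 3746 and 4999 in the stigma, which is 24.1%, 27.5% and 26.02% of the genes tested. In the ovary GLYMA_15G119200 fell from 140 ± 61.3 to 2.37 ± 0.901 FPKM (log2 fold change -5.29, SE 0.38, limma adjusted p = 1.93e-05). Pistil-enriched genes fell more often than they rose, 76 against 14 of 151 in the ovary (median -0.40, camera adjusted p = 1.28e-07) and 70 against 13 in the stigma (median -0.43, camera adjusted p = 4.66e-09). Their adjusted p was 0.0957 in the ovary and 0.621 in the stigma with an estimated correlation. Their share of ovary FPKM was 6.02% ± 0.0764 under combined stress, against 6.49% ± 0.101 in the control. In the stigma their share did not fall, at 5.35% ± 0.152 against 5.19% ± 0.0831. These shares were not tested. In the sepal, 79 sepal-enriched genes rose and 112 fell of 384 (median -0.06, camera adjusted p = 0.647), and without control replicate 3 it was 67 and 140 (median -0.22). Genes enriched in other organs also fell in the sepal, where control replicate 3 held more of their signal: 58 of 135 tested pistil-enriched genes fell and 0 rose (median -1.14, or -0.71 without that replicate, camera adjusted p = 2.41e-10, and 0.878 as the adjusted p with an estimated correlation). The excess of lower genes depended on scaling: median-of-ratios rescaling gave 3379 higher and 3943 lower in the sepal. In the ovary, leaving out the anther-enriched genes and rescaling each library to its remaining FPKM gave 4800 higher and 4511 lower. Those genes held 0.405% of ovary FPKM in the control and 0.191% under combined stress. Summed FPKM averaged 631528 in control ovaries and 599281 under combined stress, and that rescaling makes these sums equal. The ovary shift is therefore not credited to the anther-enriched genes. The stigma total of 8745 was 5790 without combined-stress replicate 2.

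In the anther, combined stress changed more genes than in any other organ, and the libraries differed in makeup. The share of FPKM from anther-enriched genes was 33.6% ± 5.44 (SD, n = 3) under combined stress, against 55.6% ± 3.24 in the control, 55.5% ± 2.43 under water deficit and 51.03% ± 3.36 under heat. Of the 1325 anther-enriched genes, 1031 fell and 114 rose (median log2 fold change -1.20, quartiles -1.57 and -0.62), while 2370 of 4240 broadly expressed genes rose and 233 fell (median 0.47, camera adjusted p = 0.117, and 0.878 with an estimated correlation). Among single genes, GLYMA_07G200500 rose from 0.231 ± 0.141 to 192 ± 130 FPKM (log2 fold change 7.10, SE 0.38, limma adjusted p = 1.12e-06). The camera adjusted p of the anther-enriched genes was 4.75e-100, and the adjusted p was 0.0957 with an estimated correlation. The difference in share was larger than the spread between replicates, with an exact two-sided permutation p of 0.1 for combined stress (n = 3), the smallest possible, and 0.2 for heat.

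Limma called 14766 genes higher and 3044 lower in the anther under combined stress, 62.4% of the 28529 tested, and the total of 17810 was 11377 after median-of-ratios rescaling and 11442 without the anther-enriched genes. The size of this excess depended on scaling, since FPKM are shares of a total. The median log2 fold change of all tested anther genes was 0.61 as deposited and 0.15 after median-of-ratios rescaling, which gave 5988 genes higher and 5389 lower. Broadly expressed genes are therefore best read relative to that median of all genes. Leaving out the anther-enriched genes and rescaling to the remaining FPKM gave 7822 higher and 3620 lower. The median of the anther-enriched genes was -1.81 after the rescaling, so their direction did not turn.

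**Figure D2:**
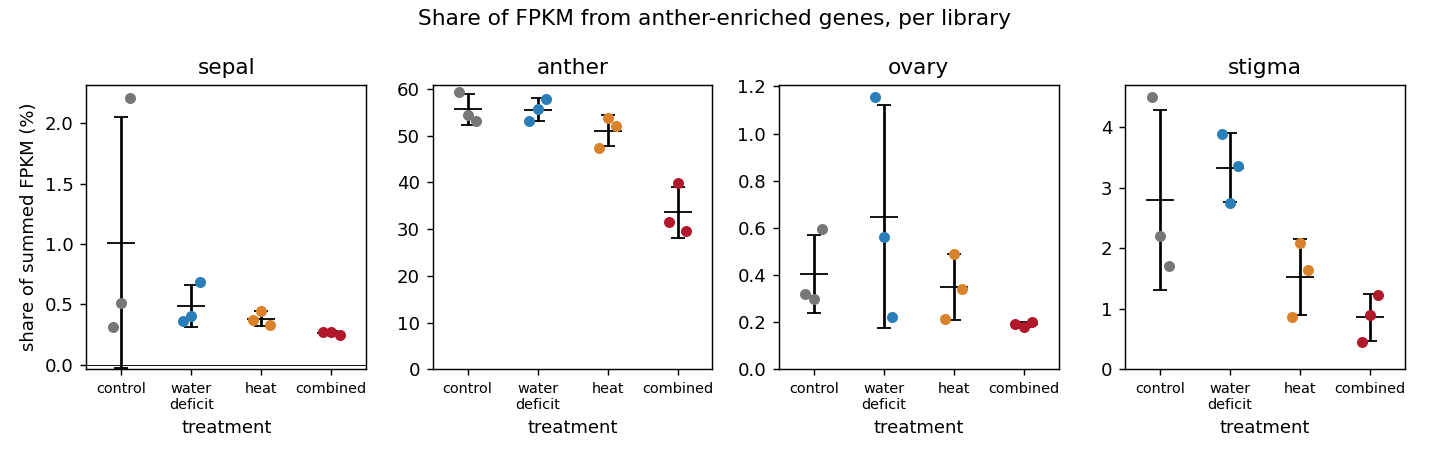
Points are single libraries and give the share of summed FPKM from anther-enriched genes in percent on the vertical axis, by treatment on the horizontal axis and with a separate scale for each organ. Black dashes and bars are the mean and SD of 3 libraries, and the anther mean was 55.6% in the control and 33.6% under combined stress.

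The anther-enriched genes were also lower under combined stress in the stigma, where 762 of 1244 tested fell and 2 rose (median -1.18, camera adjusted p = 5.47e-31, and adjusted p = 0.878 with an estimated correlation). Their share of stigma FPKM was 2.80% ± 1.49 in the control, 3.33% ± 0.571 under water deficit, 1.52% ± 0.619 under heat and 0.860% ± 0.387 under combined stress. Stigma control replicate 1 alone held 4.49%, and the median log2 fold change without it is not given here. In the ovary 57 of 656 fell and 10 rose (median -0.68), and in the sepal 150 of 803 fell and 13 rose (median -0.97). The sepal change was smaller without control replicate 3, when 77 fell and 18 rose (median -0.42). Its camera adjusted p was then 0.00086, adjusted over the gene groups of this comparison alone. The filter was set before that replicate was left out. Genes tested only through their level in that replicate therefore stayed in, which favours a fall. The 3 combined-stress libraries had a lower share than the 3 controls in every organ, each with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give. For the ovary and the sepal the camera adjusted p values were 1.09e-05 and 6.53e-10, and the adjusted p was 0.878 in both with an estimated correlation.

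**Figure D3:**
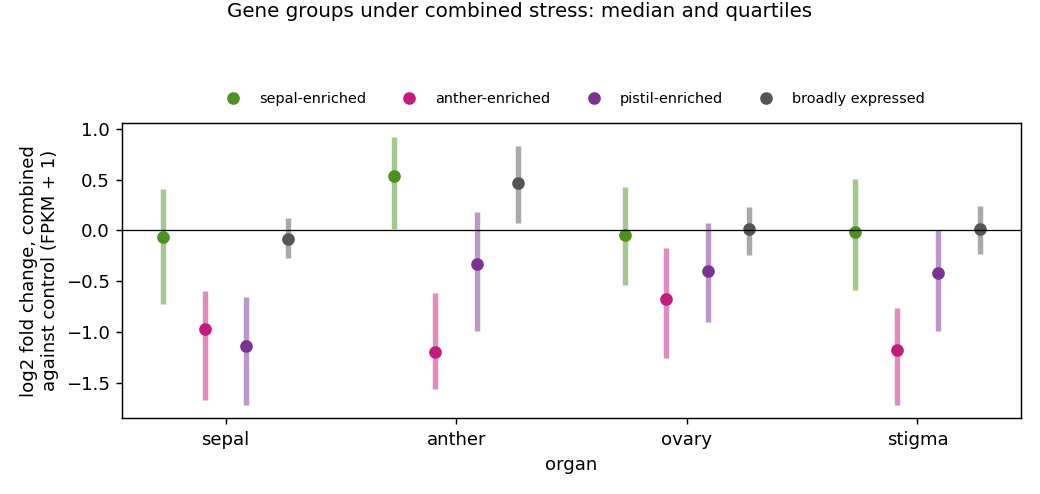
Dots are the median and bars the quartiles of the log2 fold change of FPKM + 1 under combined stress against control (vertical axis), for 4 groups of genes in each organ (horizontal axis). Anther-enriched genes lay below 0 in each organ, with medians from -1.20 in the anther to -0.68 in the ovary, and the positive anther medians of broadly expressed (0.47) and sepal-enriched (0.53) genes lie beside a median of 0.61 for all anther genes, which fell to 0.15 after rescaling.

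Combined stress was compared with heat to find what water deficit added at high temperature. In the ovary and stigma few genes differed, and those with the largest rise had already risen under heat. GLYMA_14G063700 was listed at 0 in the control stigmas and reached 24.7 ± 15.7 FPKM under heat and 267 ± 67.7 under combined stress, and in the ovary it reached 14.5 ± 5.96 and 182 ± 46.6 FPKM. Its log2 fold change of combined stress over heat was 3.52 in the stigma (SE 0.34, limma adjusted p = 0.00182) and 3.60 in the ovary (SE 0.23, limma adjusted p = 2.73e-05). GLYMA_04G229800 was listed at 0 in control ovaries and stood there at 7.04 ± 2.11 FPKM under heat and 89.3 ± 26.6 under combined stress (log2 fold change 3.48, SE 0.22, limma adjusted p = 2.73e-05). In the stigma GLYMA_05G109600 fell from 22.8 ± 5.07 to 2.29 ± 0.686 FPKM (log2 fold change -2.85, SE 0.27, limma adjusted p = 0.00137), and in the ovary GLYMA_15G119200 fell from 35.9 ± 7.50 to 2.37 ± 0.901 FPKM (log2 fold change -3.46, SE 0.38, limma adjusted p = 0.00539).

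Between combined stress and heat, 272 genes were higher and 839 lower in the sepal, 7200 and 2438 in the anther, 74 and 189 in the ovary, and 146 and 234 in the stigma. In the anther, 1052 anther-enriched genes were lower and 99 higher (median -0.90, camera adjusted p = 1.22e-102, and adjusted p = 0.0957 with an estimated correlation). Of the broadly expressed genes 1357 were higher and 96 lower, but their median of 0.26 lay below the 0.36 of all anther genes. Camera gave the opposite direction, up, and did not pass (camera adjusted p = 0.101, and 0.878 with an estimated correlation). The anther split turned with scaling, to 1218 higher and 3454 lower after median-of-ratios rescaling, and its total was 4551 without combined-stress replicate 3. Without heat replicate 3 the sepal total was 511 and the stigma total 86, and the ovary total was 59 without heat replicate 2. The call of GLYMA_14G063700 in the stigma was lost in 1 of 13 alternatives.

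**Figure D4:**
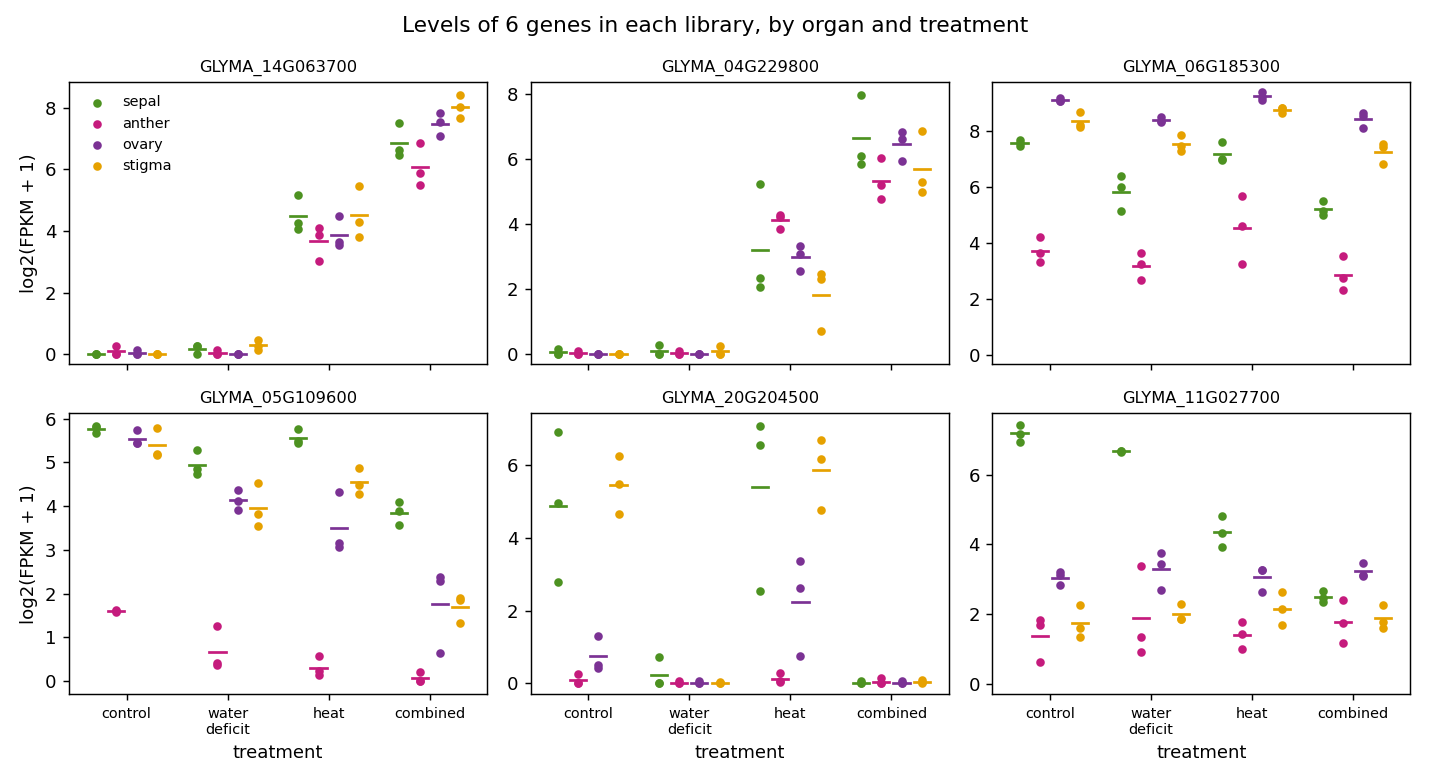
Points are single libraries and dashes are means of 3, on a log2(FPKM + 1) scale (vertical axis), by treatment (horizontal axis) and coloured by organ, for 6 genes, of which the full profiles were chosen after their values were seen. GLYMA_14G063700 and GLYMA_04G229800 stood near 0 without heat, GLYMA_20G204500 near 0 with water deficit, and GLYMA_11G027700 fell in the sepal from 145 to 4.67 FPKM under combined stress.

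Combined stress was compared with water deficit to find the effect of heat on plants that were short of water. This effect resembled that of heat on watered plants. Genes called in both comparisons, which share no library, mostly went the same way: in the sepal 741 were higher and 1491 lower in both and 8 went opposite ways, in the ovary 1188, 2501 and 8, in the stigma 1026, 1523 and 4, and in the anther 3727, 877 and 14. Independent calls would give 258 opposite genes in the sepal, 559 in the ovary, 386 in the stigma and 979 in the anther. Across genes, Spearman's rho between these log2 fold changes was 0.633 in the sepal, 0.581 in the anther, 0.657 in the ovary and 0.669 in the stigma, and genes are not independent replicates. With 1 replicate of every group left out, the genes that went the same way numbered 317 to 738 in the sepal, 341 to 2814 in the anther, 819 to 1546 in the ovary and 219 to 1060 in the stigma, and rho was 0.542 to 0.563, 0.430 to 0.660, 0.552 to 0.631 and 0.534 to 0.641. GLYMA_17G252200, lower in the sepal under heat, was also lower there under combined stress than under water deficit (59.5 ± 9.70 against 2.46 ± 1.93 FPKM, log2 fold change -4.25, SE 0.32, limma adjusted p = 4.36e-05).

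Against water deficit, combined stress gave 1631 higher and 3428 lower genes in the sepal, 14677 and 2733 in the anther, 2763 and 4331 in the ovary, and 1830 and 3770 in the stigma. After median-of-ratios rescaling these were 2191 and 2394 in the sepal and 4914 and 4814 in the anther. Without combined-stress replicate 2 the totals were 3103 in the sepal and 3092 in the stigma, and without water-deficit replicate 1 the ovary total was 4389.

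The interaction tested whether the change under combined stress differed from the sum of the separate changes on the log2 scale. In the ovary 5 genes passed. GLYMA_14G063700, GLYMA_14G063800 and GLYMA_04G229800 were higher than the sum (limma adjusted p = 0.0013 for each, n = 3 libraries per group), and their levels without heat were near or at 0. For GLYMA_14G063700 and GLYMA_04G229800 the interaction terms of 3.64 and 3.48 nearly restate their log2 fold changes of combined stress over heat. Near 0 an effect of water deficit alone can go unseen, so a departure from the sum is not separated from the low level. GLYMA_14G063800, whose identifier follows that of GLYMA_14G063700 and which was chosen after its values were seen, stood in the ovary at 0.777 ± 0.121 FPKM in the control, 1.10 ± 0.504 under water deficit, 17.4 ± 2.15 under heat and 152 ± 26.4 under combined stress. GLYMA_05G202700 and GLYMA_14G096600 were lower than the sum, with interaction terms of -2.70 and -1.61 on the log2 scale, and the call of GLYMA_05G202700 was lost in 10 of 18 alternatives. In the sepal 3 genes were higher and 11 lower than the sum, in the anther 31 and 49, and in the stigma limma called 0, where 2183 genes had an unadjusted p under 0.05. The anther count was 0 after median-of-ratios rescaling and ranged from 0 (without control replicate 2) to 2497 (without combined-stress replicate 2), the sepal count from 1 (without control replicate 2) to 19 (without control replicate 1), the ovary count from 4 to 19 (without heat replicate 1), and the stigma count from 0 to 5 (without water-deficit replicate 2).

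The response to combined stress in each reproductive organ was tested against that in the sepal. Genes called in both the ovary and the stigma mostly went the same way, with 2019 higher and 3164 lower in both and 10 opposite, where independent calls would give 1141 opposite. With 1 replicate of every group left out, 2074 to 2181 genes went the same way in both in place of 5183. GLYMA_11G027700 fell in the sepal from 145 to 4.67 FPKM and stood at 2.45 ± 1.16 and 2.78 ± 0.926 FPKM in the stigma, a difference in log2 fold change of 4.84 (SE 0.36, limma adjusted p = 3.27e-07). From 2.45 FPKM a fall as large as that in the sepal was not possible, so the difference partly restates the low stigma level. GLYMA_02G208300 rose in the sepal from 1.27 to 19.5 FPKM while it went from 11.1 ± 1.01 to 1.99 ± 0.201 FPKM in the ovary, a difference of -5.23 (SE 0.55, limma adjusted p = 1.46e-05).

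The change was higher than in the sepal for 13785 genes and lower for 1099 in the anther (25870 tested), for 1436 and 936 in the ovary (29917 tested), and for 1769 and 706 in the stigma (30291 tested). Median-of-ratios rescaling gave 3638 and 3106 in the anther, 1117 and 1220 in the ovary, and 1108 and 943 in the stigma, and it moved the median difference over all genes in the anther from 0.74 to 0.18 on the log2 scale.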

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

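Each result here was singled out because a response differed between organs, or because heat and water deficit together differed from the sum of their separate effects, by limma's test of that difference. For the anther, the tests of admixed tissue and of a lost cell type were chosen only after the result was seen, and so were the groups of genes by organ and the regroupings with main effects removed. Plain regroupings of the libraries were planned, but the strong effects of the stresses enter their spread or the tested term itself, so these counts decide nothing about chance and are given as values.

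In the sepal the interaction of heat and water deficit passed for 14 genes. Of 100 regroupings of the 12 libraries (real one included), 2 gave as many once the additive effects of heat and water deficit were removed. That share lay under 0.05, but the highest other gave 21, more than the real count, so chance is not excluded. Without that removal 1 gave as many and the highest other gave 2. The count was 0 with the replicate block and 0 with no trend or robust moderation. GLYMA_19G008700 had an interaction of -2.37 on the log2 scale (SE 0.25, limma adjusted p = 0.0241), with 9.40 ± 0.401 FPKM in the control, 14.3 ± 1.92 under water deficit, 80.2 ± 23.1 under heat and 21.7 ± 3.56 under combined stress. GLYMA_13G222100 had an interaction of -2.35 (SE 0.30, limma adjusted p = 0.0337), with 22.8 ± 6.27, 32.3 ± 7.46, 14.3 ± 1.30 and 3.31 ± 0.974 FPKM in the same order. Their calls were lost in 4 and 12 of 18 alternatives.

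In the anther the interaction passed for 80 genes, and 6 of 100 regroupings gave as many after the additive effects were removed, with 5059 as the highest other, so chance is not excluded. Without that removal 3 gave as many and the highest other gave 9372. The count was 0 after median-of-ratios rescaling, 0 with the replicate block and 0 without the anther-enriched genes. GLYMA_03G129300 had an interaction of 4.16 (SE 0.65, limma adjusted p = 0.0393), with 120 ± 19.3 FPKM in the control, 7.79 ± 1.78 under water deficit, 46.7 ± 30.5 under heat and 55.4 ± 26.1 under combined stress. Its call was lost in 12 of 18 alternatives. In the ovary the interaction passed for 5 genes, and 3 of 100 regroupings gave as many after the additive effects were removed. There too the share lay under 0.05, but the highest other gave 21, more than the real count, so chance is not excluded. Without that removal 3 gave as many and the highest other gave 26. GLYMA_05G202700 had an interaction of -2.70 in the ovary (SE 0.35, limma adjusted p = 0.0313), with 5.26 ± 0.922 FPKM under heat and 0.342 ± 0.138 under combined stress, and its call was lost in 10 of 18 alternatives. GLYMA_14G096600 had one of -1.61 (SE 0.17, limma adjusted p = 0.00416), with 3.84 ± 0.501 FPKM in the control and 9.92 ± 0.735, 11.9 ± 1.77 and 8.49 ± 0.541 under water deficit, heat and combined stress, and was called in all 18 alternatives. In the stigma limma called 0 genes, a count that any regrouping reaches, so the 100 of 100 that gave as many with the additive effects removed or kept decide nothing about chance. The highest others were 3 and 9.

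The response to combined stress differed from that of the sepal for 14884 genes in the anther, 2372 in the ovary and 2475 in the stigma. After the response common to both organs was removed, 1 of 100 regroupings, the real one, gave as many in each of the 3 comparisons. The highest others were 10527 for the anther, 67 for the ovary and 325 for the stigma, so chance is argued against in that test. Without that removal, labels turned in 1 organ make the common response a difference, and 1, 8 and 8 of 100 gave as many, with 12996, 5778 and 6132 as the highest others. GLYMA_02G208300 differed by -5.23 between ovary and sepal, with 1.27 and 19.5 FPKM in control and combined-stress sepals and 11.1 and 1.99 FPKM in such ovaries. GLYMA_11G027700 differed by 4.84 between stigma and sepal, with 145 and 4.67 FPKM in the sepal and 2.45 and 2.78 FPKM in the stigma. That low stigma level left it little room to fall.

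The lower level of anther-enriched genes in anthers under combined stress was weighed because it accompanies the large anther difference. A few abundant genes that lowered all others alike are argued against, since the median log2 fold change of all tested anther genes was 0.61. The median of the anther-enriched genes was -1.81 after median-of-ratios rescaling (quartiles -2.18 and -1.24). Factors averaged 0.865 in the control and 1.34 under combined stress, so the rescaling could only lower that median. It also takes the typical gene as unchanged, so a rise of other transcripts that lowered the share of these genes stays open. Admixed sepal or pistil tissue is argued against, since its genes rose by at most 0.862% of their level in their own organ while the anther-enriched share fell by 39.5%. Loss of 1 cell type that holds these genes in fixed proportion cannot be told apart from other changes within the anther, since 8.60% of the genes were called higher but only 2.94% after rescaling. A change in the mix of anther cell types, a change in developmental stage and lower transcript levels within cells stay open, and so does the growth chamber if each treatment had its own.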

How the results depend on the processing

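Leaving out the anther-enriched genes (always with libraries rescaled to their remaining FPKM), the 4-fold definition and the estimated correlation were added after the data were seen. The alternatives for the 28 gene lists were not run, since the lists could not be built. Of the 30 counts of genes, between 22 and 26 stayed within 1.5 times their value under each alternative that keeps every library and every group, and 13 of 20 did with only the 2 groups compared. Depth limits genes near 0, and small changes were often missed in simulated data.

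Without the anther-enriched genes the counts were 9075 in place of 14884 for anther minus sepal, and in the anther 11442 in place of 17810 for combined stress, 3361 in place of 9638 against heat, 9971 in place of 17410 against water deficit, 0 in place of 80 for the interaction and 2 in place of 1 for water deficit; the stigma interaction gave 1 in place of 0. Median-of-ratios rescaling gave 6744, 11377, 4672, 9728, 0 and 2 for the same 6 anther results. With no filter the interaction gave 41 in the anther and 4 in place of 14 in the sepal, and water deficit gave 29 in place of 69 in the sepal and 23 in place of 55 in the stigma. With no trend or robust moderation, combined stress against heat gave 149 in place of 263 in the ovary, the sepal interaction 0, and water deficit 30 in the sepal and 31 in the stigma. With only the 2 groups compared, combined stress against heat gave 6047 in the anther and 68 in the ovary, heat 1792 in place of 3748 in the sepal, and water deficit 4 in the anther, 10 in place of 78 in the ovary, 6 in the sepal and 6 in the stigma. A pseudocount of 0.1 FPKM gave 11 for the anther interaction, 1 for the stigma interaction, and for water deficit 2 in the anther and 19 in the stigma. The replicate block gave 0 for the anther and sepal interactions, 150 in the ovary and 251 in place of 380 in the stigma for combined stress against heat, and for water deficit 2 in the anther, 31 in the ovary, 19 in the sepal and 30 in the stigma, and 14723, 2209 and 2346 for the anther, ovary and stigma minus the sepal. Replicate numbers were not treated as pairs. After group means were removed, every same-numbered pair of libraries correlated above 0.1 in 0 of 24 comparisons of groups within an organ, and in 1 of 24 comparisons of organs within a treatment (sepal and stigma, combined stress). Every library correlated best with its own number in 1 of 24 of each kind. The cause of the differences between settings was not tested.

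With single libraries left out, water deficit gave 12 to 294 genes in the sepal, 0 to 7 in the anther, 4 to 116 in the ovary and 11 to 73 in the stigma. Heat gave 2096 to 3960, 2570 to 6739, 3406 to 4280 and 2272 to 3528 in that order, and combined stress 5622 to 7860, 14480 to 17873, 6960 to 7618 and 5790 to 7395. Against heat it gave 511 to 698, 4551 to 10159, 59 to 165 and 86 to 168, and against water deficit 3103 to 3658, 13942 to 17491, 4389 to 5755 and 3092 to 4883. The interaction gave 1 to 19, 0 to 2497, 4 to 19 and 0 to 5. The differences from the sepal gave 12739 to 15823 in the anther, 1759 to 2476 in the ovary and 1687 to 2385 in the stigma. With 1 replicate of every group left out, genes shared by the 4 organs numbered 196 to 327 for combined stress, 9 to 23 for heat and 0 for water deficit.

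Leaving out 1 replicate of every group moved 40 of 42 counts of genes called the same way in 2 comparisons by over 1.5 times and 25 of 42 correlations by more than their spread, and leaving out the filter moved 10 of 14 correlations. Under the 4-fold definition, 12 group shares of FPKM from anther-enriched genes moved by more than their SD and 4 did not.

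Some medians changed sign. Without control replicate 3 of the sepal, anther-enriched genes in the sepal under water deficit had a median of 0.10 in place of -0.51 (-0.93 without control replicate 1), and sepal-enriched genes in the sepal -0.0454 in place of 0.106 under water deficit and -0.0079 in place of 0.0915 under heat (0.211 and 0.196 without control replicate 1). With the 4-fold definition, pistil-enriched genes in the anther had medians of 0.13 in place of -0.33 under combined stress, 0.0245 in place of -0.14 for combined stress against heat and 0.0735 in place of -0.29 under heat. After median-of-ratios rescaling, sepal-enriched genes in the anther under heat had a median of -0.0590 in place of 0.03. The cause was not tested.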

Other observations

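The tests of the stigma, of the third sepal control and of consecutive identifiers, and the agreement between comparisons, were chosen only after the data were seen, and the splits of the libraries were planned.

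The effect of water deficit was compared across temperatures. Across genes, Spearman's rho between the water-deficit effect without heat and that with heat was 0.343 in the sepal, 0.217 in the stigma, 0.182 in the ovary and 0.0735 in the anther, and genes are not independent replicates. With 1 replicate of every group left out, rho was 0.255 to 0.297 in the sepal, 0.0866 to 0.253 in the stigma, 0.0941 to 0.176 in the ovary and -0.327 to 0.396 in the anther, where its sign turned. The genes called in both went the same way, 10 higher and 30 lower in the sepal, 4 and 19 in the ovary and 11 and 24 in the stigma, with 0 opposite, and with 1 replicate of every group left out they numbered 1 to 6, 1 to 3 and 0 to 13. GLYMA_06G185300, whose profile was chosen after its values were seen, was at 190 ± 14.4 FPKM in control sepals, 59.9 ± 24.3 under water deficit, 148 ± 40.9 under heat and 36.3 ± 6.79 under combined stress. In the ovary it was at 550 ± 18.7, 334 ± 22.3, 605 ± 58.7 and 346 ± 62.8 FPKM in the same order. Its limma adjusted p under water deficit was 0.0486 in the sepal and 0.0403 in the ovary, and the sepal call was lost in 10 of 13 alternatives.

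GLYMA_20G204500 was also near 0 with water deficit outside the stigma. In the sepal it was at 121, 30.0 and 5.97 FPKM in control libraries and 4.85, 134 and 92.5 FPKM under heat, against 0.668 FPKM in 1 library and 0 in the other 2 under water deficit. Limma's adjusted p in the sepal was 0.183 for water deficit and 0.0259 for combined stress, and the latter call was lost in 6 of 13 alternatives. Among the most abundant transcripts of the pistil, chosen after their values were seen, GLYMA_08G200100 rose in the ovary from 1971 ± 312 to 9421 ± 1124 FPKM under combined stress (log2 fold change 2.26, SE 0.14, limma adjusted p = 2.54e-06) and in the stigma from 3576 ± 454 to 14314 ± 710 FPKM (log2 fold change 2.01, SE 0.14, limma adjusted p = 1.14e-05). GLYMA_08G200000, with the preceding identifier, fell in the ovary from 8348 ± 1012 to 3013 ± 314 FPKM (log2 fold change -1.47, SE 0.12, limma adjusted p = 1.06e-05) and in the stigma from 4303 ± 366 to 843 ± 84.4 FPKM (log2 fold change -2.35, SE 0.28, limma adjusted p = 0.00029). Reads shared between copies of genes with consecutive identifiers were not tested.

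The lower level of anther-enriched genes in stigmas under combined stress was weighed as a hypothesis about what the stigma samples held. Scaling as the whole cause is argued against if the typical stigma gene is taken as unchanged, since their median log2 fold change stayed at -1.18 after median-of-ratios rescaling. Spearman's rho between control levels in stigma and anther was 0.960 over 1244 genes, so levels in these organs went together. This rho concerns control levels and not changes, and no other organ was set beside it. It therefore does not decide whether each gene fell inside stigma cells, unrelated to anther material. Less anther material in the stigma samples and the same material with fewer of these transcripts cannot be told apart. The rho of 0.466 between the changes in stigma and anther decides nothing, since the levels of the 2 organs go together and low levels shrink both changes. The stigma share was 5.04% of the anther share in the control and 2.56% under combined stress, and pollen on the stigma and carry-over at dissection were not separated.

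The third control library of the sepal stood apart from the others, and its makeup was weighed. Anther and pistil material in that library may account for this. Of its 460 genes at 4-fold or more over the other controls, 77.2% were 8-fold or more higher in another organ than in the sepal. The share was 4.88% among genes with a sepal mean of at least 0.1 FPKM. Deeper sequencing stays open beside it, with a relative depth of 1.30. The mean correlation of this library with the other controls was 0.965, against 0.969 and 0.973 for replicates 1 and 2. With genes of the other organs left out it was 0.976, against 0.978 and 0.979, still the lowest but by a small margin. Replicates 1 and 2 had 94 genes each at 4-fold or more over the others.

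Genes with consecutive identifiers were tested for similar responses to combined stress. Spearman's rho between their log2 fold changes was 0.0956 in the sepal, 0.0494 in the anther, 0.0671 in the ovary and 0.0787 in the stigma. The highest of 1000 permutations gave 0.0221, 0.0258, 0.0217 and 0.0185 in the same order. These values restate the likeness and decide nothing about its cause, and a shared response of neighbouring genes and shared reads between similar copies stay open.

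Splits of the 6 libraries of each pair of groups into 3 and 3 number 10, too few for a share under 0.05. The real split alone gave as many genes, a count of 1 split, in each comparison within the sepal, ovary and stigma and in the anther except under water deficit, where 4 splits did. In the sepal the real count and the highest other were 69 and 2 for water deficit, 3748 and 2 for heat, 7996 and 1 for combined stress, 1111 and 1 for combined stress against heat, and 5059 and 2 for combined stress against water deficit. In the anther they were 1 and 2, 5277 and 2, 17810 and 2, 9638 and 2, and 17410 and 1 in that order. In the ovary they were 78 and 2, 5610 and 6, 9154 and 1, 263 and 3, and 7094 and 2. In the stigma they were 55 and 2, 4682 and 2, 8745 and 118, 380 and 1, and 5600 and 2.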
